A study of Mus musculus with 19 samples.

How the data were processed

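RNA was measured in the livers of 19 mice, 1 library per mouse, from total RNA prepared with a NuGen Ovation mouse RNA-seq kit, per the labels' protocols. The labels give each library a genotype at Pkd1 (WT, Het or Homo, with AAV-Cre in each group) and a treatment of Western diet plus carbon tetrachloride (CCl4) for 3 months. Each sample title also ends in a number, called the mouse number here. The labels do not say what it stands for or whether it is an order. The series' design text calls the mice littermates. The labels give no sex, litter, age, batch or sequencing date, and no statement of which part of Pkd1 is deleted.

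The authors deposited 1 table of raw counts per gene symbol, with 1 column per mouse. STAR 2.7.2b, featureCounts 1.6.4 and the genome build GRCm38 are named in the submitters' processing notes. Their settings, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited counts are whole numbers with no normalization, and column totals differ between libraries. Of the 35976 rows, 27 carry a calendar date in place of a gene symbol, and 2 of these dates each name 2 rows. These rows stayed in the library totals, of which they make about 0.15% (0.150% in WT replicate 1), and no result names them. Trac, Ighm, Igkc, Iglc2 and Ahsp, members of the fixed lists, are not used here because no row has these names.

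Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16, with TMM normalization, the filterByExpr filter by genotype, which left 16463 genes, and the quasi-likelihood F test (glmQLFit and glmQLFTest). Benjamini-Hochberg adjusted p-values under 0.05 were called, two-sided. All 19 libraries entered 1 fit with genotype as its factor, so that the 3 comparisons (Homo against WT, Het against WT, Homo against Het) share 1 estimate of the spread. A separate fit took the number of mutant alleles (0, 1 or 2) as a number. CPM, each gene's counts scaled by library size, use TMM library sizes, and log2 CPM uses a prior count of 2. Every adjusted p-value of a gene below comes from edgeR's quasi-likelihood test, unless another tool is named, and ± after a log2 fold change is its standard error (SE), taken as the fold change divided by the square root of the test's F.

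The design, the tests, the alternatives and 33 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01), adjusted over the 30 lists tested. Camera with an estimated correlation and fry were run beside it. The named genes follow a rule fixed at the same time. Among called genes with an official symbol and a mean of at least 1 CPM in the higher genotype, it takes the 8 largest changes in each direction for Homo against WT, and 5 in each direction for the other comparisons and the trend. From each list it adds up to 3 members with the smallest p in Homo against WT, and it always adds Pkd1 and Pkd2. The text names most of these and gives other members of a list only as examples of its count. Genes named outside the rule are said to have been chosen after their values were seen.

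Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2's size factors in edgeR, no filter, a filter of 1 CPM in 6 libraries, a 2-fold minimum, an adjusted p under 0.10, only the 2 genotypes compared, and leaving out each library in turn. A fit with sex as a covariate had been planned for libraries that fall into 2 classes by Y-linked genes and Xist. All 19 libraries fell into 1 class, with Y-linked genes expressed, so it was not run. Alternatives with mouse number as a covariate, without mice 1 to 3, within mice 8 to 13, within mice 14 to 20, and without chromosome 17 were chosen after seeing the data.

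The scripts were tested on simulated counts drawn from the means, spreads and library sizes of these 16463 genes. For Homo against WT, edgeR recovered 55.2% of genes planted at 1.5-fold, 77.6% at 2-fold and 97.0% at 4-fold, and 4.91% of its calls were not planted. Of DESeq2's calls in the same simulation, 12.8% were not planted, and with nothing planted in Het against WT it made 13 calls against 0 by edgeR. The simulation drew each gene on its own, with no pattern over the mouse numbers. These rates therefore do not cover false calls that such a pattern could bring in these mice. Library totals ranged from 25.8 to 42.1 M counts (M for mega). No 2 libraries of a genotype agreed within sampling noise: chi-square per degree of freedom was at least 23.2 for every pair.

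Positions come from the RefSeq annotation of GRCm38, the build the processing notes name. Of the tested genes, 15367 matched it by symbol and 508 by an older symbol, and 588 had no position. Strand is not stated for the counting, so reads from a stretch shared with a gene on the other strand cannot be told apart. Of the 77 genes with a position called in Homo against WT, 43 overlap another annotated gene. Krt7, Krt19 and Klf5 overlap none.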

Results

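Livers were profiled by RNA sequencing in 7 WT, 6 Het and 6 Homo mice, all given AAV-Cre, a viral vector that carries Cre recombinase, and all kept for 3 months on Western diet plus CCl4. This regimen combines a fat- and sugar-rich diet with a liver toxin and serves as a model of non-alcoholic steatohepatitis (NASH). Pkd1 encodes polycystin-1, the protein mutated in most autosomal dominant polycystic kidney disease. Per its title, the series asks how Pkd1 mutation bears on steatohepatitis and liver cancer. Library totals, in M counts (mega, SI prefix), were 35.6 ± 2.20 in WT (SD, n = 7), 32.9 ± 4.77 in Het (n = 6) and 35.6 ± 3.64 in Homo (n = 6).

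The first principal component of log2 CPM held 11.6% of the variance and followed the mouse numbers of the labels (Pearson's r = 0.90, Spearman's rho = 0.88, each with permutation p = 1e-05, the smallest that 100000 permutations can give). Mouse 1 is the farthest from the median number, 11, and mice 2 and 20 are next and equally far: r was 0.86 without mice 1 and 2 and 0.90 without mice 1 and 20. Within WT, r was 0.98 (exact permutation p = 0.00159, rho = 0.93 with exact p = 0.00675), and 0.99 without mice 1 and 2. Within Het it was 0.94 (exact p = 0.0458, rho = 0.89 with exact p = 0.0333), and 0.96 without mice 19 and 20. Within Homo it was 0.86 (exact p = 0.0361, rho = 0.54 with exact p = 0.297), but -0.53 without mice 8 and 10, on which it rests. Adjusted over these 4 correlations, Pearson's p was 0.0458 in Het and in Homo and 0.00317 in WT. Mice 1 to 3 are all WT, and 4 of the 6 Homo mice have numbers from 15 to 18, so number and genotype partly overlap.

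**Figure D1:**
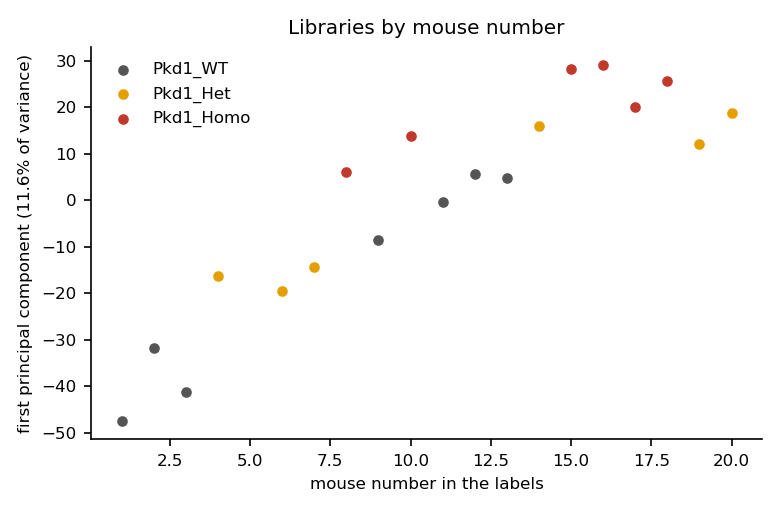
The first principal component of log2 CPM (vertical axis) of each of the 19 libraries against the mouse number in the labels (horizontal axis), coloured by genotype. WT mice 1 to 3 lie at -47.6 to -31.9, and Homo mice 15 to 18 at 20.1 to 29.1.

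Pkd1 itself (chromosome 17, 24548689 to 24596514, GRCm38) did not pass in any comparison. It was at 405 ± 38.6 CPM in WT (SD, n = 7), 390 ± 46.2 in Het (n = 6) and 357 ± 19.7 in Homo (n = 6). The log2 fold change of Homo against WT was -0.18 ± 0.08 (adjusted p = 0.315; exact permutation p = 0.0251, two-sided), that of Het against WT -0.06 ± 0.08 (adjusted p = 0.869) and that of Homo against Het -0.13 ± 0.08 (adjusted p = 0.879). Homo against WT was at -0.27 with mouse number as a covariate and at -0.34 within mice 8 to 13, not called in either. Counts over the whole gene include exons that a partial deletion leaves and cells that Cre did not reach, so they do not check the labels. Tsc2 overlaps the end of Pkd1. Pkd2, the partner channel of polycystin-1, was at 18.2 ± 5.03 CPM in WT and 22.8 ± 7.38 in Homo (log2 fold change 0.33 ± 0.25, adjusted p = 0.614).

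Homo against WT asks what differs when both alleles are mutant. Krt7 and Krt19, keratins of bile duct cells, were higher by 3.06 ± 0.40 (adjusted p = 0.00043) and 2.50 ± 0.39 (adjusted p = 0.00305) on the log2 scale. Krt19 rose from 1.19 ± 0.87 CPM in WT (SD, n = 7) to 6.76 ± 2.96 in Homo (n = 6). Cdh6, a cadherin, rose by 2.44 ± 0.34, and Gabrp, a subunit of a GABA receptor, by 3.63 ± 0.74. Klf5, an epithelial transcription factor, rose by 2.24 ± 0.39, Anxa8, an annexin, by 2.19 ± 0.48, and Tspan8, a tetraspanin, by 1.98 ± 0.39 (adjusted p of these 5 between 0.000824 and 0.0438). For Krt7, Krt19, Cdh6, Gabrp and Klf5, each of the 6 Homo mice exceeded the highest of the 7 WT and of the 6 Het mice, whereas for Tspan8 and Anxa8 the lowest Homo mouse, at 1.24 and 0.269 CPM, lay under the highest WT mouse, at 1.93 and 0.445 CPM.

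In all, 79 genes passed in Homo against WT, 48 higher and 31 lower, of 16463 tested. The proliferation gene Ccnd1 (cyclin D1) rose by 1.06 ± 0.23 (adjusted p = 0.045), from 22.9 ± 6.38 CPM in WT (n = 7) to 47.6 ± 13.6 in Homo (n = 6). Cd24a, a surface protein on the list of oncofetal markers, rose from 1.42 ± 0.58 CPM in WT (n = 7) to 4.02 ± 1.87 in Homo (n = 6; adjusted p = 0.0194). The interferon-induced genes Ifi44 and Usp18 rose by 0.88 ± 0.13 (adjusted p = 0.00178) and 0.70 ± 0.14 (adjusted p = 0.0209). Slco1a4, a transporter of bile acids and other organic anions, fell by 1.03 on the log2 scale (SE 0.21, adjusted p = 0.0248), and Sdr9c7, a short-chain dehydrogenase, fell by 0.90 (SE 0.18, adjusted p = 0.0237). The count moved by over 1.5 times when single libraries were left out. It was 41, 36, 122 and 49 without WT replicates 1, 3, 6 and 7, and 45, 35 and 41 without Homo replicates 2, 3 and 4. Of the 19 fits that each left out 1 library, the call ended in 13 for Ccnd1, 12 for Anxa8, 7 for Gabrp, 6 for Tspan8, 5 for Sdr9c7, 4 for Slco1a4, 4 for Cd24a and 3 for Usp18, with adjusted p of at most 0.118, while those of Krt7, Krt19, Cdh6, Klf5 and Ifi44 held in each. With mouse number as a covariate 38 genes were called, without mice 1 to 3 25, and within mice 8 to 13 only 2.

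**Figure D2:**
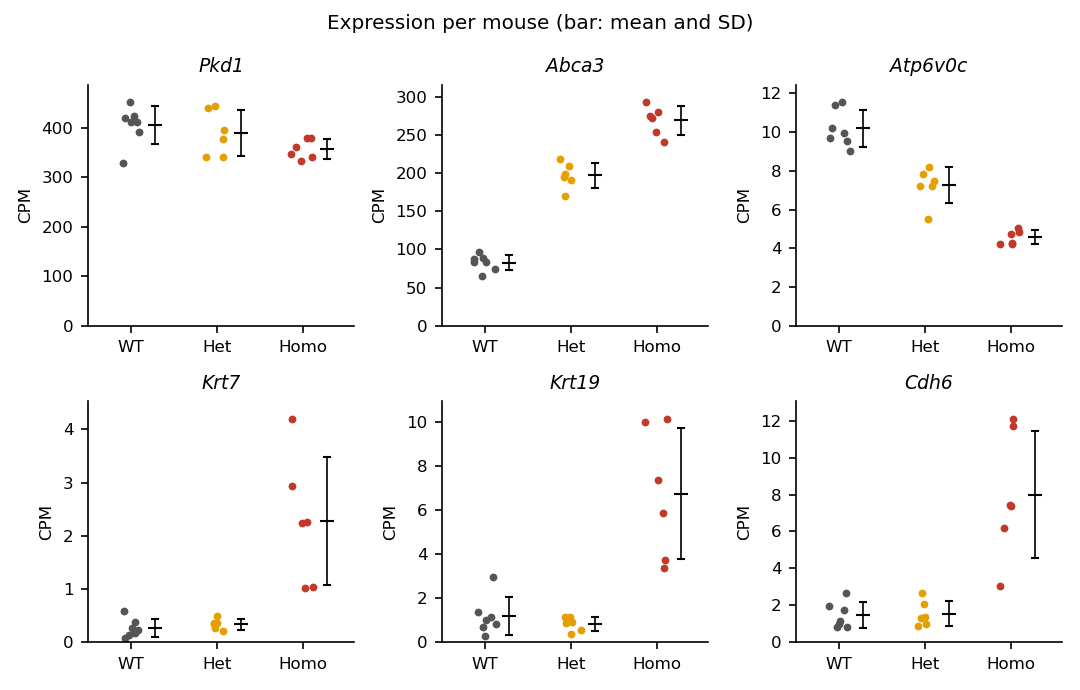
CPM of 6 genes in each mouse (points) by genotype, with mean and SD (bars), 7 WT, 6 Het and 6 Homo. Abca3 and Atp6v0c change stepwise over the genotypes, Krt7, Krt19 and Cdh6 are high in the Homo mice alone, and Pkd1 overlaps between genotypes.

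Of the 79 genes, 27 lie on chromosome 17, the chromosome of Pkd1. That is 35.1% of the called genes with a position, against 4.96% of tested genes (odds ratio 10.7, 95% interval 6.38 to 17.5, Fisher's exact p = 1.63e-16). They span from Tmem181b-ps, which starts at 6439002, to the end of Gm8909 at 36168602. Both genes were chosen after their values were seen. Of the 27, 10 lie within 1 Mb of Pkd1, and 14 were higher and 13 lower. Abca3, a lipid transporter, rose by 1.70 ± 0.08 (adjusted p = 5.87e-11), from 82.7 ± 10.1 CPM in WT (n = 7) to 269 ± 18.6 in Homo (n = 6). Atp6v0c, a subunit of the proton pump of lysosomes, fell by 1.16 on the log2 scale (SE 0.10, adjusted p = 5.78e-07), and Ccnf (cyclin F) fell by 1.63 (SE 0.21, adjusted p = 0.000433). Hmga1, a chromatin protein, fell by 1.03, Ntn3, a netrin, by 1.06, Tmem8, a membrane protein, by 0.76, and Rnps1, a splicing factor, by 0.73 (adjusted p between 0.00028 and 0.00305). Atp6v0c-ps2, a pseudogene copy of Atp6v0c on chromosome 6, rose by 4.53 ± 0.38 (adjusted p = 5.78e-07), from 0 to 6 reads per WT library to 49 to 90 per Homo library. Reads of the 2 copies can be mistaken for each other, so both values are uncertain. Reads from the short stretch where Abca3 and D330041H03Rik overlap cannot be told apart without strand.

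**Figure D3:**
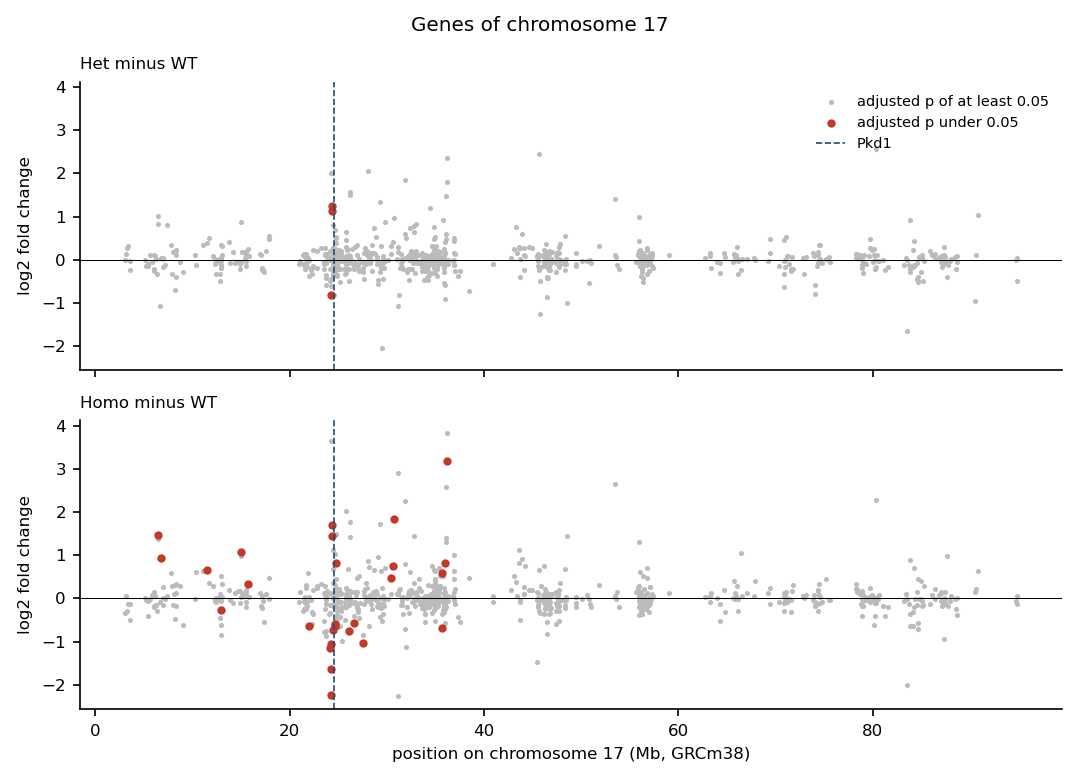
Log2 fold change (vertical axes) of each tested gene of chromosome 17 against its position in Mb (horizontal axis, GRCm38), for Het minus WT above and Homo minus WT below. Red points are called genes, of which 3 and 27 lie on this chromosome, and the dashed line is Pkd1.

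Of the 33 lists, 7 passed in Homo against WT. The bile duct list was higher, with 12 of 15 tested members above 0, a median of 0.85 and 2 members called (Krt7 and Krt19; 7 adjusted over the list alone). Its adjusted p was 8.60e-09 with camera and 0.161 with an estimated correlation. Among members not called, Epcam, an adhesion protein of duct cells, was at 0.98 ± 0.26 (adjusted p = 0.109) and Sox9, a transcription factor of duct and progenitor cells, at -0.12 ± 0.23. All 20 interferon response genes lay above 0 (median 0.38, 2 called, 7 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). The proliferation list had a median of 0.39, with 15 of 17 members above 0 and 1 called (2 adjusted over the list alone; adjusted p = 0.190 with an estimated correlation). Mki67, the antigen Ki-67 of dividing cells, was at 0.73 ± 0.18 (adjusted p = 0.0832).

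Lower lists in Homo against WT were the unfolded protein response, bile acid synthesis and transport, periportal hepatocyte genes and oxidative phosphorylation. All 18 unfolded protein response genes lay below 0, with a median of -0.34 and none called (0 also adjusted over the list alone). Dnajb9, a chaperone of the endoplasmic reticulum, was at -0.64 ± 0.24. This list followed the mouse number: Dnajb9 was at 51.3 to 51.5 CPM in WT mice 1 to 3 and at 16.4 to 31.9 CPM in the other 16 mice. Without mice 1 to 3 its direction turned (adjusted p = 0.904). The bile acid list had a median of -0.19, with Slco1a4 called and 5 members adjusted over the list alone. The periportal list, with Sds and Hal, enzymes of serine and histidine breakdown, had a median of -0.19, and 4 members passed adjusted over the list alone. All 18 oxidative phosphorylation genes lay below 0, with a median of -0.11 and none called. With an estimated correlation the adjusted p was 0.161 for bile acid genes, 0.484 for periportal genes, 0.484 for oxidative phosphorylation and 0.520 for the unfolded protein response, so camera kept none of the 7 (4 of 30 lists had an unadjusted p under 0.05). Fry, run beside it, called 5 of the 7: bile acid genes (adjusted p = 0.0134), bile duct, proliferation and interferon response (0.0181 each) and oxidative phosphorylation (0.0493). As many as 7 lists arose in 44 of 100 splits of the same libraries.

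The lists that describe steatohepatitis did not pass in Homo against WT. Closest to the threshold were fatty acid synthesis (camera adjusted p = 0.0551, 5 of 20 members above 0) and fibrosis (0.0734, 17 of 24 above 0). With an estimated correlation each had adjusted p = 0.794. For the other immune and lipid lists below, camera with the preset correlation gave adjusted p between 0.415 and 0.994. Medians were 0.12 for fibrosis and activated stellate cells, 0.01 for macrophages and Kupffer cells, 0.41 for T and NK cells, -0.02 for B and plasma cells, -0.07 for dendritic cells and 0.08 for cytokines and chemokines. Postn (periostin), a matrix protein of activated stellate cells, was at 0.53 ± 0.13 (adjusted p = 0.0775, and called adjusted over the list alone). Among lipid lists, medians were -0.16 for fatty acid synthesis, 0.06 for cholesterol synthesis, 0.04 for fatty acid oxidation and PPARA targets, and 0.01 for lipid droplets and lipid uptake. Srebf1 and Mlxipl, transcription factors of lipid synthesis, were at -0.61 ± 0.18 and -0.33 ± 0.09 (adjusted p = 0.150 and 0.125), and both passed adjusted over the list alone. Apoc3, an apolipoprotein of hepatocytes, was at -0.35 ± 0.09 and Lyve1, a marker of sinusoidal endothelium, at -0.64 ± 0.16 (adjusted p = 0.083 and 0.0907), each also passing adjusted over its list alone. Their lists, hepatocyte secreted and identity genes and endothelial cells, had medians of -0.08 and -0.05.

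Other lists not called in Homo against WT had medians of -0.02 (xenobiotic metabolism), 0.02 (pericentral hepatocytes), -0.02 (ATF4 and mTORC1 amino acid genes), -0.05 (glycolysis and hypoxia) and 0.19 (oncofetal and liver tumour markers). Medians were -0.12 for acute phase proteins, -0.00321 for NRF2 targets, 0.11 for YAP targets, -0.03 for polycystin partners and polycystic disease genes, 0.01 for male-biased genes and 0.44 for female-biased genes. The signs of median, mean and test differed for NRF2 targets, polycystin partners, male-biased genes, xenobiotic metabolism and B and plasma cells. Neutrophils, erythroid cells, and pancreas and adipocyte carry-over had under 5 tested members and no test. Their medians were -0.09 over 4 genes, -0.21 over 3 and 2.08 over 1. Of these, the 3 erythroid genes included 2 lower adjusted over the list alone. Cela1, a pancreatic elastase and the 1 tested gene of the last, was not called over all genes (adjusted p = 0.271).

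**Figure D4:**
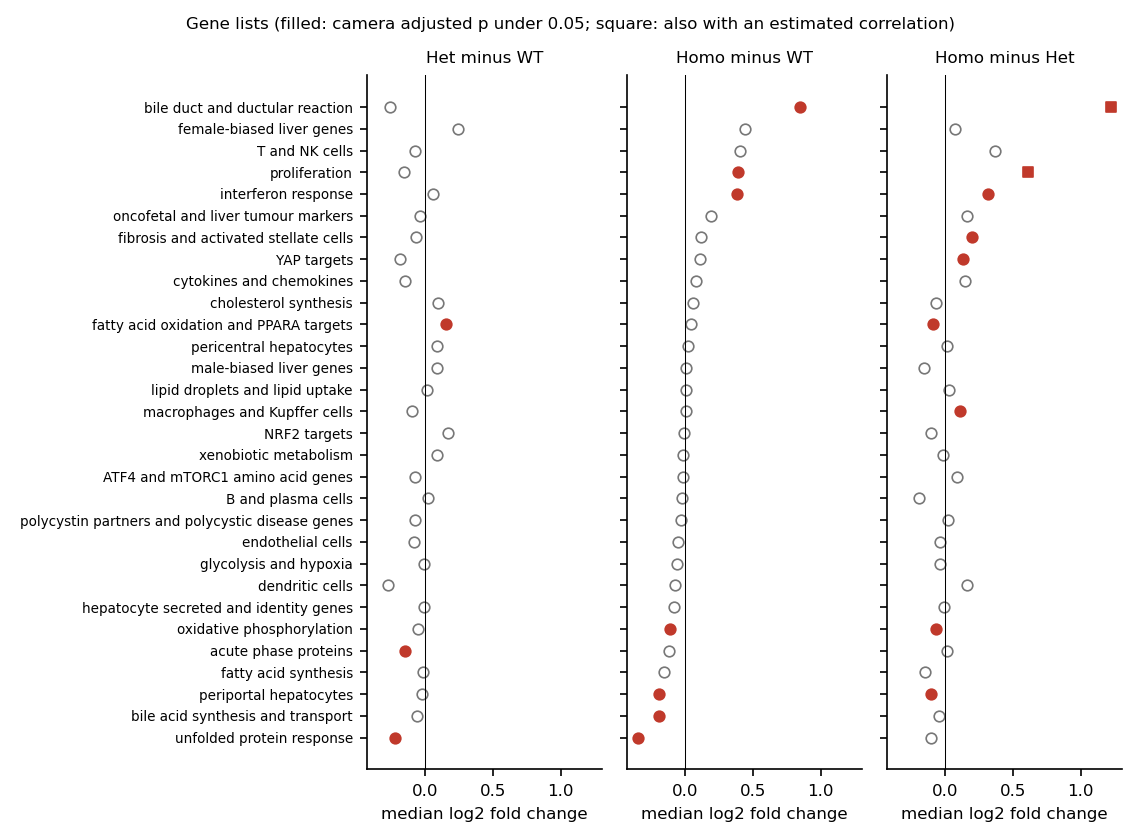
Median log2 fold change (horizontal axes) of the 30 tested gene lists (vertical axis) in the 3 comparisons. Filled symbols passed camera, 3, 7 and 9 lists from left to right, and the 2 squares, bile duct and proliferation in Homo minus Het, also passed with an estimated correlation.

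Het against WT asks for the effect of 1 mutant allele. Het livers differed from WT in 4 genes, 3 of them near Pkd1 on chromosome 17 and the other the Atp6v0c pseudogene. Abca3 rose by 1.25 ± 0.08 (adjusted p = 1.6e-08), to 197 ± 16.4 CPM (n = 6), and all 6 Het mice lay above all 7 WT mice. Atp6v0c-ps2 rose by 3.93 ± 0.38 (adjusted p = 1.33e-05). Outside the naming rule, and named because the count is 4, were D330041H03Rik, higher by 1.13 ± 0.13 (adjusted p = 0.000226), and 1600002H07Rik, now Tedc2, a tubulin-related gene, lower by 0.82 (log2 fold change -0.82 ± 0.12, adjusted p = 0.00746). At an unadjusted p under 0.05 there were 1455 genes, and DESeq2 called 28. Bile duct genes did not pass: Krt7 was at 0.32 ± 0.42 and Krt19 at -0.49 ± 0.42, and the bile duct list had a median of -0.26 (adjusted p = 0.113).

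Of the lists, 3 passed in Het against WT with camera. Fatty acid oxidation and PPARA targets were higher (median 0.16, 18 of 22 members above 0), acute phase proteins lower (-0.15) and the unfolded protein response lower (-0.22). None held with an estimated correlation, where each had adjusted p = 0.801, and fry called 0 lists. No member of the 3 was called. As many as 3 lists arose in 92 of 100 splits. The unfolded protein response list turned its direction with mouse number as a covariate (adjusted p = 0.980), and without mice 1 to 3 it passed as higher in Het (adjusted p = 0.0389). Leaving out single libraries ended its call in 6 of 19 fits, with adjusted p up to 0.263 without WT replicate 1, and the call of acute phase proteins in 4, with adjusted p up to 0.204 without Het replicate 6.

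All 4 genes called in Het against WT were also called in Homo against WT, in the same direction. Both comparisons use the same WT libraries, so the shared calls are not independent. Across genes, which are not independent replicates, the correlation of the log2 CPM differences was 0.50. Simulated unchanged groups set against the same WT libraries gave 0.47 (0.45 to 0.49 over 20 simulations). The simulations drew each gene on its own, without the pattern that follows the mouse number. Their narrow range therefore does not bound what unchanged groups of these mice would give. With disjoint sets of 3 and 4 WT libraries the observed correlation was 0.14. The covariance was 0.0596, against 0.0367 simulated and 0.0211 with disjoint WT libraries (0.00111 to 0.0282 over 35 ways to divide them).

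Homo against Het tests whether the genotypes with 1 and 2 mutant alleles differ. The bile duct markers Krt19, Krt7 and Epcam rose by 3.00 ± 0.43 (adjusted p = 0.00496), 2.74 ± 0.42 (adjusted p = 0.00575) and 1.38 ± 0.28 (adjusted p = 0.0437), and Kcne3, a potassium channel subunit, by 2.59 ± 0.48. Tspan8, Klf5, Cdh6 and Cd24a were higher by 2.55 ± 0.43, 2.43 ± 0.42, 2.35 ± 0.36 and 1.76 ± 0.31. In all 30 genes passed, 24 higher and 6 lower, against 102 with DESeq2 and 16 with limma-voom. Within mice 14 to 20 (3 Het and 4 Homo) edgeR called 0, with 874 genes at an unadjusted p under 0.05. Chance alone puts tested genes under that p at a rate of 0.05, so 874 by itself does not show a difference. Among those 7 mice, which also took part in calling the 30 genes, their fold changes had a median ratio of 0.813 to those from all mice. Lower were 1600002H07Rik, outside the rule, at -1.42 ± 0.13, Atp6v0c (-0.67 ± 0.10), Gtf2h4, a subunit of the transcription factor TFIIH (-0.65 ± 0.10), Tmem8 (-0.54 ± 0.10), Rnps1 (-0.48 ± 0.09) and Map3k11, a kinase (-0.36 ± 0.07). Abca3 was again higher, by 0.45 ± 0.08 (adjusted p = 0.0258).

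Of the lists, 9 passed in Homo against Het, and bile duct and proliferation held with an estimated correlation (adjusted p = 0.00833 for each). In the bile duct list 14 of 15 members lay above 0, with a median of 1.23 and 3 called (7 adjusted over the list alone). In the proliferation list 16 of 17 did, with a median of 0.61 and none called (5 adjusted over the list alone), among them Top2a, the topoisomerase of dividing cells, at 0.81. Against WT, Het lay lower in the proliferation list, though it was not called (median -0.15, 6 of 17 members above 0, camera adjusted p = 0.156). The distance of Homo from Het was thus wider than that from WT (median 0.39). Interferon response (median 0.32), fibrosis and activated stellate cells (0.20), YAP targets (0.13) and macrophages (0.11) were higher. Their adjusted p with an estimated correlation was 0.127, 0.394, 0.127 and 0.622. In Het against WT their medians were 0.06, -0.07, -0.19 and -0.10, none called. Oxidative phosphorylation (-0.07), periportal genes (-0.10) and fatty acid oxidation (-0.09) were lower, with adjusted p of 0.617, 0.508 and 0.622 by that test. Within mice 14 to 20 the direction turned for macrophages, fatty acid oxidation and oxidative phosphorylation (adjusted p = 0.766, 0.848 and 0.310). As many as 9 lists arose in 26 of 100 splits. The gene count was 13, 12 and 9 without Het replicates 1, 2 and 3, and 17, 12 and 11 without Homo replicates 1, 2 and 3. Without Homo replicate 2 the list count was 4. Of the 19 fits that each left out 1 library, the call ended in 14 for Map3k11, 12 for Epcam, 10 for Rnps1, 9 for Tmem8, 8 for Kcne3 and for Abca3, 5 for Cd24a, 4 for Klf5 and 1 for Tspan8 (adjusted p up to 0.134), and in 7 for macrophages, 6 for fatty acid oxidation, 4 for periportal genes and for oxidative phosphorylation and 1 for YAP targets (adjusted p up to 0.486).

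The trend over 0, 1 and 2 mutant alleles was called for 74 genes, 43 rising and 31 falling, of which 27 lie on chromosome 17. With mouse number as a covariate 29 genes were called, and 25 without mice 1 to 3. Per allele, Krt7 rose by 1.56 ± 0.22, Krt19 by 1.26 ± 0.25, Gabrp by 1.88 ± 0.38 and Atp6v0c-ps2 by 2.05 ± 0.31. Slco1a4 fell by 0.53 on the log2 scale (SE 0.11), Ccnf by 0.81, Atp6v0c by 0.58, Ntn3 by 0.53 and Hmga1 by 0.51 (adjusted p of these 9 between 3.83e-07 and 0.0287). Slco1a4 was at 46.9 ± 11.9 CPM in WT, 24.4 ± 5.69 in Het and 22.9 ± 7.32 in Homo, so the Het mean lay close to that of Homo. Krt7 at 0.341 ± 0.10 CPM in Het lay close to WT, at 0.271 ± 0.17. In mean CPM, the Het difference from WT was -6.38% of the Homo difference for Krt19 and -0.91% for Gabrp. The slopes of these 3 genes thus come from the Homo mice and not from a step at each allele. Syt8, a synaptotagmin, had no reads in any WT library, 0.411 ± 0.65 CPM in Het and 1.36 ± 1.20 in Homo. The count was 45 and 33 without WT replicates 1 and 3, and 39, 30, 41 and 45 without Homo replicates 2, 3, 4 and 6. The calls of Slco1a4 and Gabrp ended in 6 and 5 of these fits, with adjusted p up to 0.0806.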

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

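Over 183 groups of 6 or 7 mice examined for a single mouse far from its group, 6 stood out, fewer than the 9.15 that chance gives at 1 in 20. Tspan8 was at 1.23 log2 CPM in Het replicate 6, with the next Het mouse at -0.30. Atp6v0c was at 2.48 in Het replicate 5, below the next at 2.86. Cyp2e1, a pericentral detoxifying enzyme, was at 10.01 in Het replicate 1, below the next at 10.64. Trib3, a stress-induced pseudokinase, was at -1.06 in Het replicate 4, below the next at 0.40. Cela1 was at 3.96 in Het replicate 5, above the next at 0.79. The share of mitochondrial counts was 4.75% in WT replicate 7, with the next WT library at 4.17%.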

How the results depend on the processing

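Alternatives that use mouse number, leave out mice 1 to 3, keep a run of mouse numbers or leave out chromosome 17 were chosen after seeing the data. Where no reason is given the cause was not tested. No paired analysis was possible because each mouse has its own number and replicate numbers follow accession order. A sex covariate was not run.

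For genes of Homo against WT (79), counts with a 2-fold minimum, an adjusted p under 0.10, DESeq2, mouse number, without mice 1 to 3 and without chromosome 17 were 38, 176, 305, 38, 25 and 52. Within mice 8 to 13, with 4 WT and 2 Homo, 2 genes were called, 1600002H07Rik and Abca3, with 1099 at an unadjusted p under 0.05. For Het against WT (4) DESeq2 called 28, and 1 remained without chromosome 17. For Homo against Het (30) the 2-fold minimum, adjusted p under 0.10, DESeq2 and limma-voom gave 19, 51, 102 and 16. Within mice 14 to 20, with 3 Het and 4 Homo, edgeR, the only tool run there, called 0 (874 at an unadjusted p under 0.05), with a median fold ratio of 0.813. Chance alone puts tested genes under an unadjusted p of 0.05 at that rate, which bears on the 874 and on the 1099 above. For the trend (74) the 2-fold minimum over both alleles, adjusted p under 0.10, DESeq2, mouse number, without mice 1 to 3 and without chromosome 17 gave 35, 188, 303, 29, 25 and 47. Thresholds and fewer genes or mice account for part of these by construction, and DESeq2 also made more false calls in simulation. Counts with size factors, no filter, the CPM filter and only the 2 genotypes stayed within 1.5 times.

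Of 7 lists in Homo against WT, 0 held with an estimated correlation, and within mice 8 to 13 there were 14. Of 3 in Het against WT, 0 held with an estimated correlation, fry or mouse number, and without mice 1 to 3 there were 6. Over all 30 lists tested, 1, 2 and 6 had an unadjusted p under 0.05 in the first 3 of these settings. The 3 lists themselves had unadjusted p of 0.156 to 0.331 with an estimated correlation and 0.108 to 0.273 with fry. Of 9 in Homo against Het, 2 held with an estimated correlation and 2 with fry, and mouse number gave 14. Directions turned for the unfolded protein response in Homo against WT without mice 1 to 3 and within mice 8 to 13 (adjusted p = 0.904 and 0.590), and in Het against WT with mouse number and without mice 1 to 3 (0.980 and 0.0389, the last a call in the other direction). They turned for macrophages, fatty acid oxidation and oxidative phosphorylation in Homo against Het within mice 14 to 20 (0.766, 0.848 and 0.310).

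Pkd1 in Homo against WT was at -0.27 with mouse number, -0.26 without mice 1 to 3 and -0.34 within mice 8 to 13. The correlation of Het and Homo changes was 0.14 with disjoint WT libraries. Leaving out 1 library at a time gave 35 to 122 genes in Homo against WT, 4 to 7 in Het against WT, 9 to 34 in Homo against Het and 30 to 107 in the trend. Lists ranged from 7 to 10, 2 to 5 and 4 to 12, and Pkd1 from -0.23 to -0.16. Het against WT reached 7 genes without WT replicate 6 and 5 lists without WT replicate 3 or Het replicate 3. None of the 41 named gene values past the threshold changed sign. Depth limits genes with few reads, such as Atp6v0c-ps2 with 0 to 6 reads per WT library.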

Other observations

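Further genes called in Homo against WT, none on a fixed list and all chosen here after their values were seen, were Ano1, Muc1, Itgb4, Lama5, Bcam and Ahnak. Ano1, a chloride channel of secretory epithelia, rose from 23.4 CPM in WT to 62.0 in Homo (log2 fold change 1.41 ± 0.26, adjusted p = 0.0161). Muc1, an epithelial mucin, was higher by 1.83 ± 0.37, Itgb4, an integrin that binds laminin, by 1.05 ± 0.19, and Lama5, a laminin chain, by 0.96 ± 0.18 (adjusted p of 0.025, 0.012 and 0.0194). Bcam, a laminin receptor, was higher by 1.36 ± 0.17 (adjusted p = 0.000358), and Ahnak, a large scaffold protein, by 0.75 ± 0.12 (adjusted p = 0.00297).

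Cela1 was at 15.5 CPM or more in 3 mice, Het replicate 5 and Homo replicates 1 and 5 (18.6 and 24.6 CPM), and at 3.02 CPM or less in the other 16.

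The tests of explanations in the next 3 paragraphs were all chosen after the results were seen. The first pattern is the gathering of called genes on chromosome 17. An effect of Pkd1 loss only on close neighbours is argued against by 13 called genes more than 5 Mb away, among 601 tested (odds ratio against other chromosomes 6.65, 95% interval 3.29 to 12.5). A stretch of chromosome inherited together with the mutant allele would put Het midway, and this stays open. With no WT library in both differences, the Het mice had a median of 40.3% of the Homo difference, where no Het change gives 0. It ranged from 10.7 to 61.3% over 70 partitions of the WT libraries. The lowest value came from the partition that set Homo against WT mice 1 to 3 alone, with 803 genes called off this chromosome. For called genes elsewhere the median was 6.14% (-8.32 to 66.4% over the same partitions). With all WT libraries in both differences, 23 of the 27 genes lay between 25 and 75%. Ezr, Ddr1 and Gtf2h4, picked after their values were seen and more than 5 Mb from Pkd1, lay at 2.64, -12.4 and 4.15%, so not all of the 13 were midway. All 27 called genes of the chromosome lie between 6439002 and 36168602, around Pkd1. Reads that moved from Atp6v0c to its copy are argued against as the whole cause of its lower level, since Atp6v0c-ps2 gained only 33.0% of that loss. The SE of 3.53 on this share covers the gain alone and takes the loss as fixed. The sum of both was 10.3 ± 0.92 CPM in WT (SD, n = 7) and 6.5 ± 0.80 in Homo (n = 6). A part of the loss, or reads dropped because they match both copies, stays open. So does an effect of Pkd1 loss itself, since the Pkd1 allele is inherited together with its neighbours.

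The second pattern is the rise of bile duct genes in Homo. A lower share of hepatocytes would raise all other cell types alike. The bile duct median, however, exceeded that of the endothelial, macrophage and stellate lists by 0.82, and their own median was 0.03. The permutation p of 1e-05, the smallest possible, came from shuffling genes and not mice. It takes genes that move together as independent, so it does not measure the spread between mice. With an estimated correlation the bile duct list itself had camera adjusted p = 0.161. A single library as the source is argued against for Krt7 and Krt19, which were both called in all 19 fits that left out 1 mouse. These are the 2 called members of the list, and the 13 others are not covered. With mouse number as a covariate Krt7 was higher by 3.07 ± 0.44, against 3.06 ± 0.40 without it. Allowing for the order of the mice thus hardly changed its rise, which speaks for Krt7 alone and not for the list. More bile duct cells, or bile duct genes switched on in other cells of Homo livers, stay open and untested (15 of the 18 listed genes were tested, and 1 stands on another list).

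The third pattern is the order of the mice. Of the called genes not placed on chromosome 17, 2 have no position. With mouse number as a covariate, the fold changes of the 34 higher ones had a median ratio of 0.995 to those without it. That ratio was 0.939 to 1.01 with each library left out, and 1.03 within mice 8 to 13, where Cnksr2 was not tested. The 18 lower ones had ratios of 0.761 (0.719 to 0.805) and 0.57. Allowing for the order thus changed the higher ones little and shrank the lower ones. The mice of these fits also took part in calling the genes, and that choice alone holds the ratios above 0. The ratios therefore do not decide whether the order is the source, in whole or in part, of either set. Over these 52 genes the median SE went from 0.19 to 0.20. Yet among all genes tested, only 18 not placed on chromosome 17 were called with the covariate and 8 without mice 1 to 3. These need not be among the 52: on all chromosomes, 31 of 38 and 21 of 25 such calls were also among the 79. For the lower unfolded protein response the order may be the source, since without mice 1 to 3 the list had adjusted p = 0.904 in the other direction. What the mouse number stands for is not in the labels, and no biological explanation of it was tested.

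At 100 splits of the libraries per comparison, no other split reached the gene counts of Homo against WT, Homo against Het and the trend. That is 1 of 100, the smallest share these splits can give. Splits mix the mouse numbers, so they do not set genotype apart from the mouse order. In Homo against WT 1 split, the real one, gave 79 genes, and the highest other gave 5. In Homo against Het it was 1 split with 30 genes, the highest other giving 1, and in the trend 1 split with 74, the highest other giving 0. Without chromosome 17 the real splits of these comparisons gave 52, 21 and 47 genes, and the highest others 1, 1 and 0. In Het against WT 4 splits, the real one among them, gave at least 4 genes, and the highest other gave 594. That split set all 6 mice numbered 7 or less against 7 mice with higher numbers, so it points to the mouse order as a structure of the samples. For the list counts chance could not be excluded. As many lists came from 44 splits in Homo against WT (7 lists, highest other 15), from 92 in Het against WT (3, highest other 14) and from 26 in Homo against Het (9, highest other 14). Taken singly, the lists called in Homo against WT reached their camera p in 2 of 100 splits (bile acid genes), 3 (bile duct, proliferation), 5 (oxidative phosphorylation), 6 (interferon response), 9 (periportal genes) and 19 (unfolded protein response). In Homo against Het it was 1, the real split, for bile duct and proliferation, 2 for YAP targets, 3 for fibrosis, 5 for interferon response, 23 for oxidative phosphorylation, 25 for periportal genes, 26 for macrophages and 41 for fatty acid oxidation, and 1 also for polycystin partners, a list not called there. In Het against WT it was 9 for fatty acid oxidation, 31 for acute phase proteins and 41 for the unfolded protein response, and 1 for bile acid genes, a list not called there.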
